A study of Mus musculus with 4 samples.

How the data were processed

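The series holds 4 RNA-seq libraries of mouse hematopoietic stem cells, 2 from wild-type (Dis3fl/fl) and 2 from Dis3-/- (Dis3fl/fl;Mx-Cre) marrow on a C57BL/6 background. Per the labels' protocols, marrow of either genotype was grafted into lethally irradiated CD45.1 hosts, and Cre was switched on by 300 µg of pIpC (a synthetic double-stranded RNA that induces interferon and with it the Mx promoter) on days 0 and 2. Stem cells were sorted on day 4 as lineage-negative, EPCR-positive, CD150-positive and CD48-negative cells, 100 cells to a library. Libraries were made by RamDA-seq, a full-length total RNA method that primes reverse transcription with not-so-random primers, followed by Nextera XT tagmentation, per the labels' protocols. Wild-type donors carried no Cre transgene, per the labels. That wild-type mice received pIpC is read from protocol text shared by both genotypes, as no label gives it by mouse.

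The submitters' processing notes name Trim Galore 0.6.6, STAR 2.7.8a, RSEM 1.3.3 and the mm10 genome build. The role of each tool, the gene annotation and the strand setting are not given in the sources used here. One deposited table held expected counts (estimated counts per gene, not normalized) for 24411 genes in the 4 libraries, and about 92.3% to 92.6% of its values were exactly whole (tolerance 0), values of 0 included. A second deposited table by the authors held TPM (transcript abundance scaled by gene length to a common total), each column of which summed to 1000000. Expected counts divide reads shared by several genes by estimate, so that values of near-identical copies, such as histone genes and pseudogenes, are uncertain. Reads of a gene and of a partner that overlaps it on the other strand cannot be told apart where strand was not used. No mitochondrially encoded gene and 0 columns of other samples were in the tables analysed here.

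Library totals of expected counts were 6818535 and 6251761 in the wild-type and 6085367 and 6442740 in the Dis3-/- libraries. In these libraries 3 counts, the floor used for a gene without reads, amount to 0.432, 0.476, 0.505 and 0.469 CPM on TMM-scaled library sizes. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. The gene with the most reads, the ribosomal RNA precursor Rn45s, took 8.35%, 8.66%, 9.10% and 8.87% of counts, and Lars2, which has a stretch resembling ribosomal RNA, took 1.30%, 1.41%, 1.70% and 1.51%. No pair of libraries held identical values. Between replicates the chi-square per degree of freedom over genes was 3.59 (wild type) and 4.24 (Dis3-/-). These values exceeded counting noise, which does not tell separate samples from repeat preparations. Replicates were kept apart because the design text gives 2 mice per genotype; nothing else in the labels describes how replicates were separated.

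Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with genotype as group (minimum count 10, minimum total 15), TMM scaling, estimateDisp, glmQLFit and a 2-sided glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 12244 genes. Fold changes are Dis3-/- over wild type on the log2 scale, with a standard error (SE) taken as the size of the log2 fold change over the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, as mean ± SD over 2 libraries. The common biological coefficient of variation was 0.0861 and the prior degrees of freedom 11.7. Gene symbols were matched to the RefSeq GRCm38.p6 table (24290 matched, 1096 of them by an older symbol), and mm10 coordinates and gene classes come from that table. Strands, transcript lengths and GC content come from GENCODE M21 on the same assembly.

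A total of 35 gene lists (processes, cell types and RNA classes) were fixed before the data were examined, as were the designs, the alternatives and the rule for named genes. The 29 lists with 5 or more tested genes were tested with camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and adjustment over lists. The rule named Dis3; the 10 largest called log2 fold changes up and down among genes with a mean CPM of at least 10 whose libraries did not overlap between genotypes, predicted (Gm) and RIKEN (Rik) gene models left out; the 3 largest up and down among those models within the same limits; and up to 4 members per list with the smallest p. It named 147 genes, and the 117 called ones are given with their values, except for some that are not reported here; of the others, Malat1 and Ddx3y were picked after their values were seen. Cdkn1a, Mdm2, Miat, Mid1, Erdr1, Rn45s, Lars2 and the sort marker genes Procr, Slamf1 and Cd48 lie outside the rule and were chosen after their values were seen.

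The procedure was tested on simulated counts for this comparison, drawn for 12244 genes with 200 genes changed, 199 of which passed the filter. It recovered 49.3% of 67 genes changed by a fold of 1.5, 76.1% of 67 changed by a fold of 2 and 98.5% of 65 changed by a fold of 4; 2.63% of its 152 calls were unchanged genes. Alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (minimum count 30), robust empirical Bayes, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) with and without a mean TPM minimum of 1, limma on log2(TPM + 0.1), a replicate block, leaving out each library in turn, a log2 fold threshold of 1, an estimated inter-gene correlation and fry. A run without Rn45s and Lars2 and counts for long noncoding RNA genes were added after seeing the data.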

Results

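Dis3-/- hematopoietic stem cells were compared with wild-type cells 4 days after the first pIpC injection. The comparison asks how gene expression changes when Dis3, a catalytic subunit of the RNA exosome, is targeted by Cre; the exosome is the complex that degrades and trims RNA from its 3' end. Each genotype had 2 libraries of 100 sorted cells. Depth ranged from 6085367 to 6818535 counts per library, with 14785 to 14874 genes above 0. Replicate libraries correlated at 0.982 over genes in either genotype (Pearson, log2 CPM), and libraries of different genotype at 0.956 to 0.959. Genes are not independent replicates.

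Dis3 (chromosome 14, 99076634 to 99099780, mm10) stood at 54.5 ± 1.91 CPM (SD, n = 2) in wild-type and at 26.9 ± 4.68 CPM in Dis3-/- libraries. Its counts were 388 and 335 in wild-type and 140 and 193 in Dis3-/- libraries. The log2 fold change was -1.02 ± 0.14 (SE; edgeR adjusted p = 2.58e-04). The floxed part of the gene is not given in the sources used here, so reads from outside the deleted part are counted too, and the annotation of Dis3 overlaps that of Pibf1. Among 4 tested neighbours of Dis3 on its chromosome, the transcription factor gene Klf12 fell (-0.88 ± 0.15, edgeR adjusted p = 1.07e-03; 1 gene also adjusted over the list alone).

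**Figure D1:**
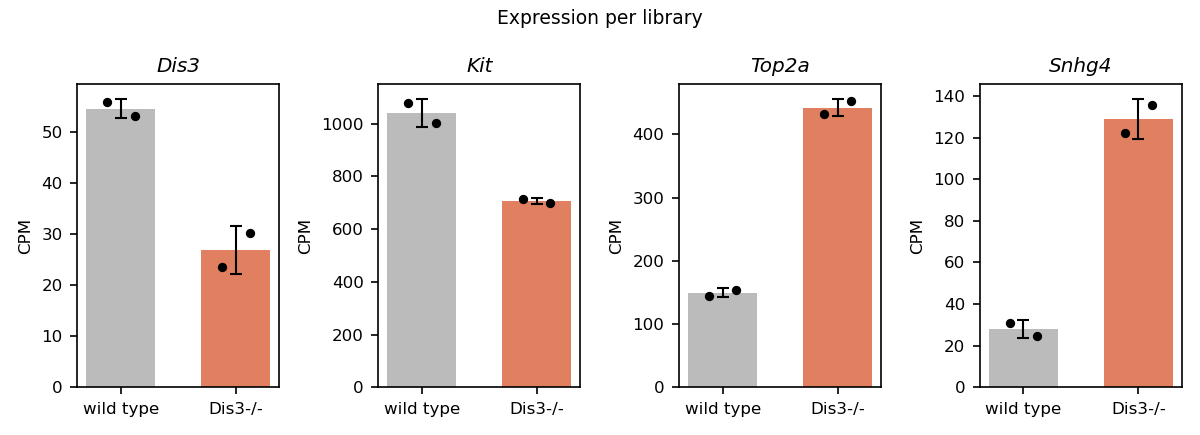
CPM of Dis3, Kit, Top2a and Snhg4 in wild-type and Dis3-/- stem cells, with bars for the mean of 2 libraries, error bars for the SD and points for single libraries. Dis3 and Kit were lower and Top2a and Snhg4 higher in both Dis3-/- libraries, with Dis3 at 54.5 against 26.9 CPM.

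Expression of 2811 of the 12244 tested genes (23.0%) differed between genotypes. In Dis3-/- stem cells 1561 genes were higher and 1250 lower. A log2 fold change of at least 1 was reached by 333 of the higher genes, and of at most -1 by 191 of the lower genes. Among genes with a mean of at least 10 CPM, predicted and RIKEN gene models left out, the widest rise was that of Slc15a2 (chromosome 16, 36750161 to 36785158), a peptide transporter gene. It had 0 counts in both wild-type libraries and 241 and 259 counts in the Dis3-/- libraries, at least 179-fold higher against a floor of 3 counts over the wild-type group. The long noncoding RNA gene BC031361 (chromosome 16, 38085064 to 38089260) stood at 1.77 ± 1.16 against 23.4 ± 2.68 CPM, a log2 fold change of 3.69 ± 0.33. Next came the protocadherin gene Fat1 (2.46 ± 0.29), the mitotic gene Gtse1 (2.46 ± 0.20), the linker histone gene Hist1h1b (2.44 ± 0.22) and the nuclease gene Ankle1 (2.42 ± 0.21). Hist1h2bk (2.42 ± 0.18), the chemokine gene Cxcl10 (2.34 ± 0.28), the abscission gene Cep55 (2.33 ± 0.28) and the small nucleolar RNA host gene Snhg4 (2.20 ± 0.12) followed. Fat1 did not pass on TPM values (limma adjusted p = 0.0512 to 0.0625).

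The steepest falls by the same rule included Il10ra, which encodes an interleukin 10 receptor subunit (25.5 ± 0.149 against 5.83 ± 3.25 CPM, log2 fold change -2.11 ± 0.28). The phosphodiesterase gene Pde2a (-2.07 ± 0.23), Sgsm1 (-2.05 ± 0.24), the chromatin organiser gene Satb1 (-1.93 ± 0.20) and the growth factor receptor gene Pdgfrb (-1.88 ± 0.26) fell as well. So did the chemokine gene Ccl4 (-1.86 ± 0.36), Hnf4a (-1.77 ± 0.24), the integrin gene Itga9 (-1.76 ± 0.20), Neb (-1.68 ± 0.39) and Mdga1 (-1.62 ± 0.12). Ccl4 overlaps Ccl3 in the annotation, so reads of this pair can be shared. The Neb call rested on 1 library: without wild-type replicate 1 its log2 fold change was -0.73 (edgeR adjusted p = 0.211). It also ended with robust empirical Bayes (0.162), DESeq2 (0.129) and TPM values. The edgeR adjusted p of these 20 genes ranged from 4.31e-08 (Slc15a2) to 7.51e-03 (Neb).

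Among predicted and RIKEN gene models with a mean of at least 10 CPM and no overlap between genotypes, D730005E14Rik (3.47 ± 0.15), G530011O06Rik (2.79 ± 0.10) and 2700038G22Rik (2.13 ± 0.29) rose most. 5830416P10Rik (-1.27 ± 0.22), Gm973 (-1.12 ± 0.25) and 2610035D17Rik (-0.92 ± 0.29) fell most within the same limits. Gm973 was not called without wild-type replicate 1 (-0.83, edgeR adjusted p = 0.0516). 2610035D17Rik was not called with DESeq2 (adjusted p = 0.114), on TPM values, without wild-type replicate 2 (-0.58, edgeR adjusted p = 0.308) or without Dis3-/- replicate 1 (edgeR adjusted p = 0.106). D730005E14Rik overlaps the coding gene Apobec3 and G530011O06Rik lies within Mid1, so their reads can be shared with those genes.

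**Figure D2:**
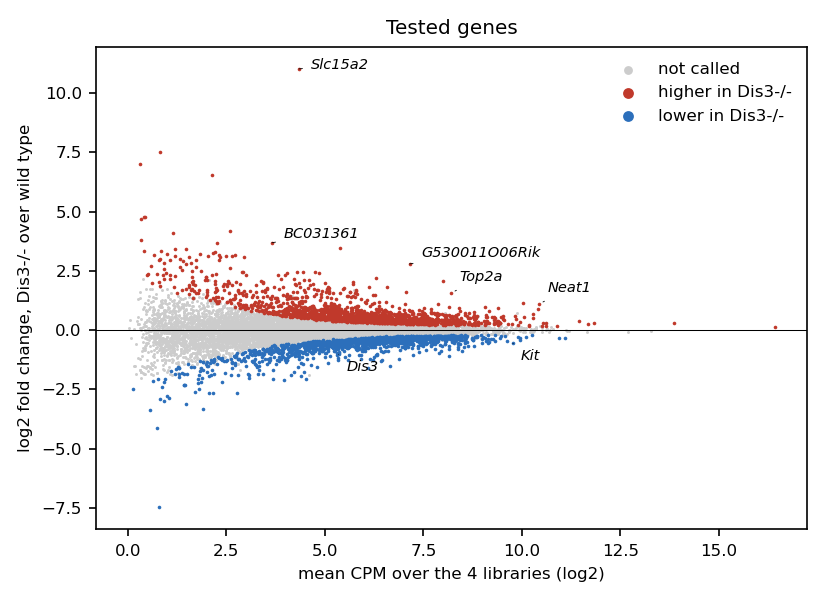
Log2 fold change of the 12244 tested genes (Dis3-/- over wild type, vertical axis) against mean CPM over the 4 libraries (log2, horizontal axis), with the 1561 genes called higher by edgeR in red and the 1250 called lower in blue. The fitted value of Slc15a2, which had no wild-type count, depends on the prior count and is no estimate of its fold.

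Genes of cell division formed the most strongly raised group. Of 61 tested genes of the G2 and M phases 59 rose (60 adjusted over the list alone), with a median log2 fold change of 1.39. The topoisomerase gene Top2a stood at 150 ± 7.08 against 442 ± 13.7 CPM (1.57 ± 0.08). The spindle motor gene Kif11 (1.81 ± 0.10), the cyclin gene Ccna2 (1.81 ± 0.13) and the proliferation marker gene Mki67 (0.92 ± 0.07) rose too. Of 60 S phase genes 47 rose (52 adjusted over the list alone; median 0.668). They included the ribonucleotide reductase genes Rrm1 (0.99 ± 0.07) and Rrm2 (1.47 ± 0.11) and the nucleotide synthesis genes Tyms (1.32 ± 0.11) and Tk1 (1.46 ± 0.13). Of 43 replication-dependent histone genes 32 rose (35 adjusted over the list alone; median 1.56). Hist1h1b, Hist1h2bk, Hist2h2bb (1.57 ± 0.14) and Hist1h4i (4.20 ± 0.47) were among them, though near-identical copies make single histone values uncertain. The camera adjusted p was 3.13e-28 for G2 and M phase, 1.98e-19 for S phase and 6.39e-19 for histone genes. With an estimated correlation each of these lists had a camera adjusted p = 0.293. Lists of unlike estimated correlation, such as G2 and M phase (0.470) and DNA damage genes (0.00436), shared that value. The Benjamini-Hochberg adjustment tied them, so the value does not tell lists apart. The unadjusted camera p in that setting was 0.117 for G2 and M phase, 0.0589 for S phase and 0.0841 for histone genes.

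Genes of growth and energy metabolism were raised by smaller amounts. Of 77 nuclear genes of the respiratory chain 53 rose and 1 fell (62 and 2 adjusted over the list alone; median 0.526). Examples were Atp5b (502 ± 8.30 against 744 ± 13.4 CPM, 0.57 ± 0.06) and Atp5g3 (0.68 ± 0.08) of the ATP synthase, Cyc1 (0.82 ± 0.10) and Ndufa4 (0.71 ± 0.09). Over genes, log2 fold changes were lower the longer the transcript (Spearman -0.230). After removal of the median of genes of like length and GC content, the respiratory chain list kept 66.7% of its median. Of 70 ribosome biogenesis genes 38 rose and 1, Dis3 itself, fell (51 and 1 adjusted over the list alone; median 0.350). Npm1 (0.60 ± 0.07), Mybbp1a (0.59 ± 0.08) and Tcof1 (0.64 ± 0.09), genes of nucleolar proteins, were among the higher. Of 27 growth genes linked to Myc and E2F 22 rose (22 higher and 1 lower adjusted over the list alone; median 0.475), such as Ran (0.81 ± 0.07), Cad (0.79 ± 0.08) and Eif5a (0.58 ± 0.07). The camera adjusted p was 5.29e-16 for respiratory chain, 4.06e-11 for ribosome biogenesis and 1.16e-08 for growth genes, and with an estimated correlation the adjusted p = 0.293 for each.

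Of 81 cytosolic ribosomal protein genes 10 rose (8 adjusted over the list alone). They included Rps27l (0.94 ± 0.12), Rpl41 (0.48 ± 0.06), Rpl14 (0.30 ± 0.07) and Rps2 (0.28 ± 0.05). Rpl14 was not called without wild-type replicate 1 (0.26, edgeR adjusted p = 0.0502), and neither Rpl14 nor Rps2 on log2(TPM + 1) values. The list's median of 0.0668 did not pass camera (adjusted p = 0.0777) and became -0.0381 on TPM values. The list passed with DESeq2 statistics (camera adjusted p = 0.0241), with limma-voom (0.0104) and without Dis3-/- replicate 2 (0.0139).

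Genes of the stem cell state were lower more often than higher. Of 54 stem cell genes 21 fell and 2 rose (22 and 2 adjusted over the list alone; median -0.253). Txnip, which encodes a thioredoxin-binding protein, fell from 459 ± 2.41 to 278 ± 2.60 CPM (-0.72 ± 0.07). The stem cell factor receptor gene Kit (-0.56 ± 0.06) fell too. The camera adjusted p of the list was 2.29e-04, and the adjusted p = 0.293 with an estimated correlation. Procr (0.04 ± 0.13, edgeR adjusted p = 0.853) and Slamf1 (-0.10 ± 0.21, edgeR adjusted p = 0.787), the genes of the sort markers EPCR and CD150, did not pass the test. Without wild-type replicate 1 or Dis3-/- replicate 1 the value of Slamf1 was above 0 (0.29 and 0.03), and that of Procr was below 0 on TPM values and without wild-type replicate 2 or Dis3-/- replicate 2 (-0.0029 and -0.059). Cd48 stood at 20.9 ± 4.64 against 14.0 ± 0.302 CPM (-0.57 ± 0.21, edgeR adjusted p = 0.0627), and passed without wild-type replicate 1 (-0.78, edgeR adjusted p = 0.0208) and without a filter on low counts (0.0312).

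In the lists of other blood cells, the genes that edgeR called were lower in Dis3-/- cells. Of 12 multipotent and lymphoid progenitor genes 7 fell (9 adjusted over the list alone; median -0.524, camera adjusted p = 1.32e-03; adjusted p = 0.293 with an estimated correlation), including Satb1, the cytokine receptor gene Flt3 (-0.89 ± 0.13) and Wfdc17 (-3.35 ± 0.64; -5.28 without Dis3-/- replicate 1). Of 16 megakaryocyte genes 5 fell (5 adjusted over the list alone; median -0.427, and -0.706 without wild-type replicate 1; camera adjusted p = 0.0101, but adjusted p = 0.293 with an estimated correlation and fry adjusted p = 0.101). These included the receptor genes F2r (-0.43 ± 0.11) and F2rl2 (-0.85 ± 0.23), and Treml1 (-2.91 ± 0.72). The call of F2r ended without Dis3-/- replicate 2 (-0.24, edgeR adjusted p = 0.110). That of F2rl2 ended without Dis3-/- replicate 1 (-0.58, edgeR adjusted p = 0.0999) and with DESeq2. That of Treml1, with 1 and 4 counts in the Dis3-/- libraries, ended without wild-type replicate 1 (-2.60, edgeR adjusted p = 0.0999) and without Dis3-/- replicate 1 (-2.30, edgeR adjusted p = 0.0965).

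Of 12 erythroid genes 4 fell (4 adjusted over the list alone; median -0.252, camera adjusted p = 0.0279; adjusted p = 0.293 with an estimated correlation). The erythroid regulator gene Gata1 stood at 13.4 ± 3.67 against 3.34 ± 0.518 CPM (-2.01 ± 0.32). The others were the water channel gene Aqp1 (-1.60 ± 0.39), the transporter gene Mfsd2b (-1.75 ± 0.49) and the carbonic anhydrase gene Car2 (-0.28 ± 0.08). Aqp1 was not called without Dis3-/- replicate 2 (-1.10, edgeR adjusted p = 0.0674), and Car2 without wild-type replicate 2 (-0.22, edgeR adjusted p = 0.104) or Dis3-/- replicate 2 (-0.19, edgeR adjusted p = 0.116). Mfsd2b was not called without wild-type replicate 1 (-1.14, edgeR adjusted p = 0.282) or Dis3-/- replicate 1 (-1.41, edgeR adjusted p = 0.0766), nor with DESeq2. The list did not pass without wild-type replicate 1 (camera adjusted p = 0.0540), wild-type replicate 2 (0.137) or Dis3-/- replicate 1 (0.0764), without a filter (0.253) or on TPM values (0.313 to 0.427), and its median was -0.468 without Dis3-/- replicate 2.

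Of 7 endothelial and stromal genes 2 fell (2 adjusted over the list alone; median -0.670, camera adjusted p = 0.0306; adjusted p = 0.293 with an estimated correlation), Pdgfrb and the adhesion molecule gene Pecam1 (-0.67 ± 0.10). The list did not pass without wild-type replicate 1 (camera adjusted p = 0.0774), wild-type replicate 2 (median -0.394, 0.344) or Dis3-/- replicate 1 (median -0.300, 0.0677), nor without a filter on low counts (0.489 on counts and 0.909 on TPM). Of 5 granulocyte genes 3 fell (3 adjusted over the list alone): the colony-stimulating factor receptor gene Csf3r (-0.74 ± 0.08), the protease gene Prtn3 (-0.67 ± 0.18) and Gstm1 (-0.31 ± 0.09). Prtn3 was not called without wild-type replicate 1 (-0.49, edgeR adjusted p = 0.127) or Dis3-/- replicate 2 (-0.61, edgeR adjusted p = 0.0646), and Gstm1 not without wild-type replicate 1 (0.0655), wild-type replicate 2 (0.0765) or Dis3-/- replicate 1 (0.130); DESeq2 called neither. The granulocyte list had a camera adjusted p of 0.0730 and passed with DESeq2 statistics (0.0134), limma-voom (0.0308) and without Dis3-/- replicate 2 (0.0468). Of 9 monocyte and macrophage genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.218), the integrin gene Itgam (-1.39 ± 0.19) and the lysosomal gene Psap (-0.36 ± 0.07).

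Both tested mast cell genes fell (2 adjusted over the list alone). They were the protease gene Cpa3 (-1.47 ± 0.47, edgeR adjusted p = 0.0366) and the transcription factor gene Gata2 (-0.27 ± 0.07, edgeR adjusted p = 0.0202). Gata2 also belongs to the stem cell list, so Cpa3 (9.60 ± 4.61 against 3.47 ± 2.47 CPM) was the only tested gene outside that list. The Cpa3 call ended without wild-type replicate 2 (-0.88, edgeR adjusted p = 0.309) or Dis3-/- replicate 2 (-0.87, edgeR adjusted p = 0.201), with robust empirical Bayes, with DESeq2 and on TPM values, and its value was -2.46 without Dis3-/- replicate 1. The Gata2 call ended without wild-type replicate 1, wild-type replicate 2 or Dis3-/- replicate 1 (edgeR adjusted p = 0.0640, 0.0907 and 0.0503). By edgeR 0 of 4 B cell and 0 of 7 T and NK cell genes were called. Adjusted over the list alone, by DESeq2 and by limma-voom the count was 0 as well, and 1 and 2 genes had an unadjusted p under 0.05. The B cell median of -0.313 was 0.0278 without wild-type replicate 1, and without wild-type replicate 2, with 5 genes tested, the list passed camera downward (median -0.585, adjusted p = 8.70e-03). The camera adjusted p was 0.907 for T and NK cell genes.

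**Figure D3:**
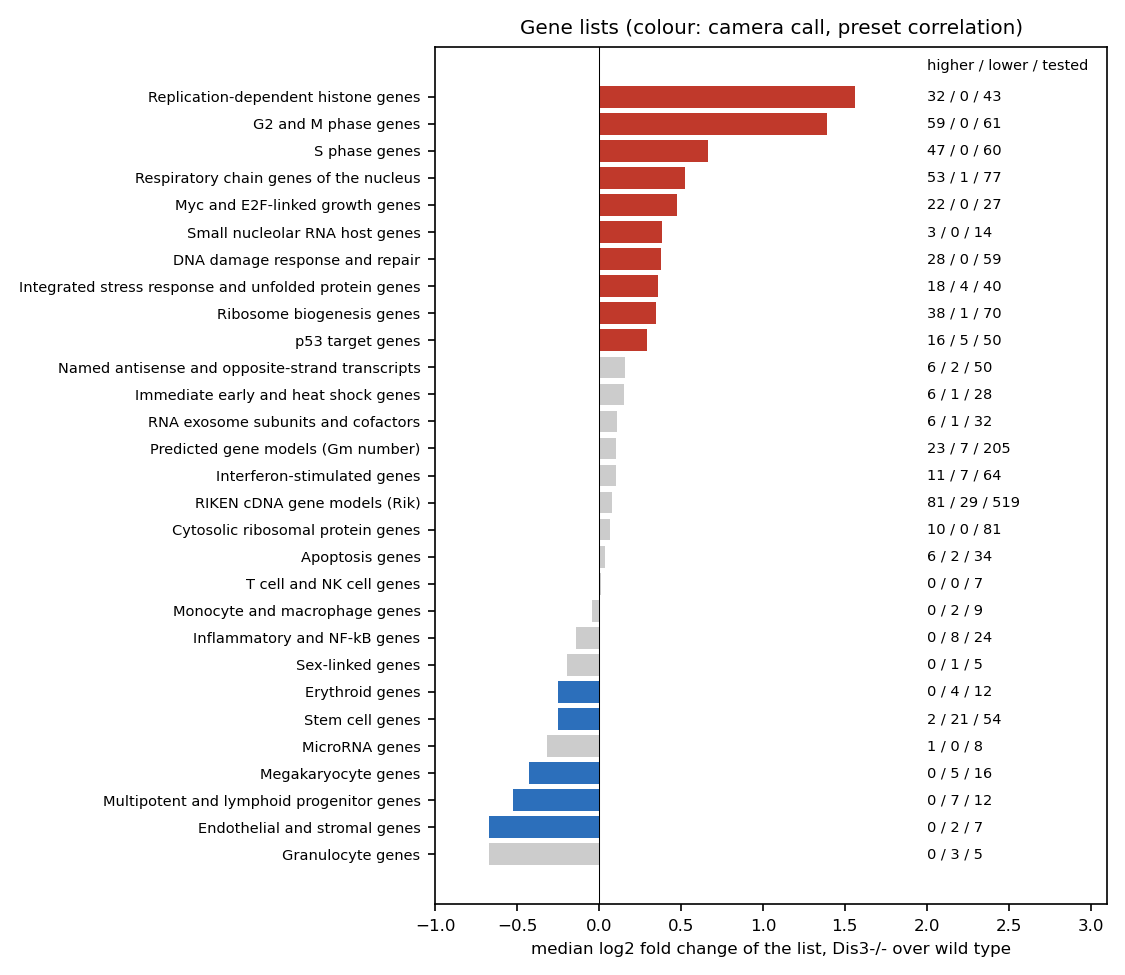
Median log2 fold change (Dis3-/- over wild type, horizontal axis) of the 29 tested gene lists, with the number of members higher, lower and tested at the right. Red and blue bars passed camera with the preset correlation and grey bars did not; G2 and M phase genes had a median of 1.39 and stem cell genes of -0.253, while the medians of the exosome, interferon, immediate early, apoptosis, ribosomal protein, antisense, RIKEN and predicted lists were below 0 in at least 1 setting on TPM values and that of T and NK cell genes with upper-quartile scaling.

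Genes of DNA repair and of p53 responses were raised in part. Of 59 genes of the DNA damage response 28 rose (32 adjusted over the list alone; median 0.381), and 7 of the list's genes also belong to the S phase list. The repair gene Brca1 rose from 55.5 to 112 CPM, a fold of 2.01 with an SE of 0.11 on the log2 scale. Fancd2 (1.53 ± 0.19), the ligase gene Lig1 (0.66 ± 0.08) and Topbp1 (0.61 ± 0.08) rose too. Of 50 p53 target genes 16 rose and 5 fell (18 and 5 adjusted over the list alone; median 0.295, and 0.140 without wild-type replicate 1). Those that rose included the receptor gene Eda2r (2.16 ± 0.22), Zmat3 (1.27 ± 0.11) and the proapoptotic gene Bax (22.1 ± 2.97 against 44.3 ± 2.85 CPM), and also Gtse1 and Psrc1 (1.94 ± 0.22), known as genes of mitosis. Of the 48 members outside the cell cycle lists, Psrc1 among them, 14 rose and 5 fell (median 0.266). This split was not fixed beforehand, and its unadjusted camera p was 9.28e-04, or 0.234 with an estimated correlation. The camera adjusted p was 2.25e-09 for DNA damage genes (adjusted p = 0.293 with an estimated correlation) and 7.28e-04 for p53 genes (adjusted p = 0.305 with an estimated correlation).

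The p53 ligase gene Mdm2 stood at 112 CPM in either genotype (0.00 ± 0.09, edgeR adjusted p = 0.991), with values on either side of 0 across settings. The cell cycle inhibitor gene Cdkn1a was lower (-0.42 ± 0.14, edgeR adjusted p = 0.0499). Its call ended without wild-type replicate 2 (-0.32, edgeR adjusted p = 0.185) or Dis3-/- replicate 2 (-0.19, edgeR adjusted p = 0.366), with DESeq2 and on TPM values, and its value without Dis3-/- replicate 1 was -0.67.

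Stress responses moved less evenly. Of 40 genes of the integrated stress and unfolded protein responses 18 rose and 4 fell (19 and 5 adjusted over the list alone; median 0.357, camera adjusted p = 3.94e-03; adjusted p = 0.293 with an estimated correlation). The serine and glycine metabolism genes Psat1 (0.79 ± 0.09) and Shmt2 (0.67 ± 0.09) and the chaperone gene Hsp90b1 (0.57 ± 0.08) rose, and the lipoprotein receptor gene Vldlr fell (-1.29 ± 0.11). Of 34 apoptosis genes 6 rose and 2 fell (7 and 3 adjusted over the list alone; median 0.0345, and -0.0733 on log2(TPM + 1); camera adjusted p = 0.305). The cytochrome c gene Cycs (1.16 ± 0.11), Aifm1 (0.94 ± 0.14), Bax and the necroptosis gene Mlkl (0.74 ± 0.14) were among the higher. Of 28 immediate early and heat shock genes 6 rose and 1 fell (8 and 2 adjusted over the list alone). The heat shock genes Hsp90aa1 (0.58 ± 0.06), Hspd1 (0.71 ± 0.09) and Hspa8 (0.39 ± 0.04) were higher and the immediate early gene Nr4a1 lower (-0.52 ± 0.07). That list did not pass camera (adjusted p = 0.228) but did without Dis3-/- replicate 1 (7.78e-04). Its median of 0.155 became -0.138 without Dis3-/- replicate 2 and -0.0229 on TPM values.

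Interferon-stimulated genes went both ways: of 64 genes 11 rose and 7 fell (12 and 7 adjusted over the list alone). Cxcl10 (5.24 ± 0.681 against 26.4 ± 10.2 CPM), Slfn2 (1.34 ± 0.26), Usp18 (0.84 ± 0.18) and Ly6e (0.52 ± 0.08) were among the higher. The list did not pass camera (median 0.106, adjusted p = 0.140). It passed without wild-type replicate 1 (6.69e-04), and its median was -0.0385 without wild-type replicate 2 and -0.00431 on TPM values. Of 24 inflammatory genes 8 fell (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0960). They included the chemokine genes Ccl3 (-3.11 ± 0.61) and Ccl4, the early response gene Ier3 (-0.53 ± 0.10) and the ribonuclease gene Zc3h12a (-0.50 ± 0.11), whose call ended without wild-type replicate 2 (-0.34, edgeR adjusted p = 0.0776). This list passed with DESeq2 statistics (camera adjusted p = 0.0398), limma-voom (0.0456), without wild-type replicate 1 (0.0488) and without Dis3-/- replicate 2 (0.0468).

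Among noncoding RNA genes, hosts of small nucleolar RNAs were raised as a list. Of 14 genes 3 rose (4 adjusted over the list alone; median 0.387, camera adjusted p = 1.40e-03; adjusted p = 0.293 with an estimated correlation). They were Snhg4 (28.0 ± 4.27 against 129 ± 9.68 CPM), Dancr (1.21 ± 0.18) and Snhg20 (1.10 ± 0.21). After removal of the median of genes of like length and GC content, the 12 hosts with a known length kept 65.2% of their median (0.305 to 0.199). Of 4 tested genes of abundant nuclear RNAs, the paraspeckle RNA gene Neat1 rose (884 ± 44.4 against 1900 ± 391 CPM, 1.10 ± 0.10; 1 gene also adjusted over the list alone). Malat1, the gene of a nuclear speckle RNA, did not pass (-0.07 ± 0.05, edgeR adjusted p = 0.350) except without Dis3-/- replicate 2 (-0.18, edgeR adjusted p = 8.53e-03), and was at 0.03 without Dis3-/- replicate 1. Small nucleolar RNA genes gave 0 calls among 4 tested by edgeR, DESeq2 and limma-voom, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. On log2(TPM + 1), where 59 such genes were tested, the list passed camera upward (median 0.455, adjusted p = 0.0473), but not on log2(TPM + 0.1) (0.0503). The microRNA list had 8 tested members, 4 of them long noncoding host genes such as Mir17hg, and Mir6236 was higher (0.29 ± 0.09, edgeR adjusted p = 0.0279; 1 gene also adjusted over the list alone; camera adjusted p = 0.337). That call ended without wild-type replicate 2 (0.20, edgeR adjusted p = 0.206) or Dis3-/- replicate 1 (0.24, edgeR adjusted p = 0.0880) and with DESeq2.

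Of 519 RIKEN gene models 81 rose and 29 fell (76 and 28 adjusted over the list alone; median 0.0807, camera adjusted p = 0.0772), with A630072M18Rik (1.73 ± 0.19) and the coding gene 2810417H13Rik (1.58 ± 0.14) among the former. Of 205 predicted gene models 23 rose and 7 fell (21 and 6 adjusted over the list alone; median 0.106, camera adjusted p = 0.178, and 0.0330 without wild-type replicate 1). Gm15441 (3.26 ± 0.46), Gm2518 (2.43 ± 0.36) and Gm6793 (0.93 ± 0.11) rose. Gm5464 had 1 and 0 wild-type and 41 and 68 Dis3-/- counts, a ratio of 117 (95% exact binomial interval 20.6 to 4660, which covers counting error only). After removal of the length and GC trend, the 164 predicted models with a known length kept 19.5% of their median (0.133 to 0.026). On log2(TPM + 1) both lists passed camera upward (adjusted p = 0.0468), with medians of -0.0318 and -0.00325, below 0. Gm15441 overlaps Txnip, which fell, and Gm5464, Gm2518, Gm6793, A630072M18Rik and BC031361 overlap other coding genes, so reads can be shared within these pairs.

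The list of symbols of antisense form had 50 tested members, of which 16 were coding genes. Among them 6 rose and 2 fell (4 and 0 adjusted over the list alone; median 0.160, camera adjusted p = 0.452). After removal of the length and GC trend the median of 45 members with a known length went from 0.158 to 0. Phtf1os (2.06 ± 0.31), Rab26os (2.95 ± 0.48), Ggnbp2os (1.05 ± 0.24) and Brip1os (0.35 ± 0.10) rose, and reads of their partners cannot be told apart where strand was not used. Ggnbp2os was not called without Dis3-/- replicate 2 (0.88, edgeR adjusted p = 0.0623). Brip1os was not called without wild-type replicate 1 (0.29, edgeR adjusted p = 0.144) or Dis3-/- replicate 2 (0.32, edgeR adjusted p = 0.0824), with DESeq2 or on TPM values.

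Of 32 genes of the exosome and its cofactors 6 rose and 1, Dis3, fell (6 and 1 adjusted over the list alone; median 0.107, and -0.0108 on TPM values; camera adjusted p = 0.0772). The core subunit genes Exosc7 (0.57 ± 0.12) and Exosc5 (0.65 ± 0.19) and the cofactor gene Wdr61 (0.63 ± 0.17) rose. Exosc5 was not called without wild-type replicate 2 (0.58, edgeR adjusted p = 0.0849) or Dis3-/- replicate 1 (0.48, edgeR adjusted p = 0.165), nor with DESeq2. Wdr61 was not called without wild-type replicate 2 (0.32, edgeR adjusted p = 0.149) or on TPM values, and was at 1.03 without wild-type replicate 1. DESeq2 called 3 genes of this list, against 7 by edgeR.

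Of 5 sex-linked genes 1 fell (2 adjusted over the list alone; camera adjusted p = 0.182). The Y-linked gene Ddx3y was present in all 4 libraries (90.2 ± 4.69 against 74.6 ± 5.38 CPM, edgeR adjusted p = 0.0656), and passed with upper-quartile scaling (0.0458) and without Dis3-/- replicate 1 (-0.35, edgeR adjusted p = 0.0469). Xist, the X inactivation RNA gene, was lower (-1.12 ± 0.38, edgeR adjusted p = 0.0498). On log2(TPM + 1) without a filter Xist stood at -0.45 and was not called (limma adjusted p = 0.22). Its call ended without each library in turn (edgeR adjusted p = 0.0751 to 0.213) and with DESeq2.

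Across lists, 10 passed camera upward and 5 downward with the preset correlation. With an estimated correlation 0 passed and 1 had an unadjusted p under 0.05. That setting raised p even where the estimated correlation was below the preset 0.01. For DNA damage genes (0.00436) the unadjusted camera p went from 4.65e-10 to 0.0198, and for exosome genes (-0.0224) from 0.0471 to 0.151. Correlation between genes therefore cannot account for the rise of p in those lists. In lists of higher estimated correlation, such as G2 and M phase genes (0.470), its part cannot be told apart. Fry, which asks only whether genes of a list move on balance, called 12 and 5, with the exosome, RIKEN and granulocyte lists in and the megakaryocyte list out. On TPM values the median of all tested genes shifted from -0.0027 to -0.106 (log2(TPM + 1)) and -0.112 (log2(TPM + 0.1)). The share of calls that were higher shifted from 55.5% to 45.3% (805 higher, 973 lower) and 44.7% (890 higher, 1102 lower). Those runs changed the values, the scaling and the test together; with RLE and upper-quartile scaling of counts 54.5% and 51.2% of calls were higher. Cre was present in Dis3-/- cells alone, and that both genotypes received pIpC is read from shared protocol text.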

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

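The runs without Rn45s and Lars2, and those on long noncoding RNA genes, were chosen after the result was seen; the former gave 1612 higher and 1235 lower genes. Dis3 kept its direction and call in each alternative, at -1.21 to -0.85 when a library was left out. With 1561 genes higher and 1250 lower as reported, DESeq2 gave 1000 and 742 (its 1742 calls were all among the reported ones, in the same direction), log2(TPM + 1) 805 higher, log2(TPM + 0.1) 890 higher, log2(TPM + 1) without a filter 479 and 471, and a log2 fold change of at least 1, a stricter rule, 333 and 191; the cause was not tested. Leaving out 1 library gave 1226 to 1319 higher and 886 to 1060 lower genes, the lone library being assumed to vary like the other group. Lists higher numbered 10 to 12 and lists lower 3 to 7 (3 without Dis3-/- replicate 1) when a library was left out. Lists lower numbered 3 without a filter and 3 on log2(TPM + 1) without a filter, against 5, and with an estimated correlation 0 lists passed in either direction. The replicate block gave 1463 higher and 1151 lower genes (2552 of the calls shared) and changed no count of lists. It ended the calls of Cpa3, Cdkn1a and Xist (edgeR adjusted p = 0.0581, 0.0601 and 0.0651). Deviations of same-numbered libraries from their group means correlated at -0.0293 over genes. No pairing by number showed in the values, though shared handling of such libraries is not excluded. Robust empirical Bayes does not enter camera. Long noncoding RNA genes higher numbered 34 on log2(TPM + 1) without a filter and 49 without Dis3-/- replicate 2, against 87; those lower 27 without a filter and 7 with DESeq2 or log2(TPM + 1) without a filter, against 17. Of the 147 genes the rule named, 117 were called, and 74 of these kept the call in every setting run. Of the other 43, 11 lost it in a count setting with all 4 libraries, 21 without a library and 40 on TPM values, where log2(TPM + 1) without a filter alone ended 40 calls; a gene can count more than once. Over 2339 alternative values of these genes 2196 kept side and direction, 113 lost the call, 22 gained it and 8 reversed, with 0 reversals in called genes. Of the genes named in the text, those that reversed were not called, and among them Malat1 alone belongs to the 147: Mdm2 at -0.0034 (RLE), -0.021 (upper quartile), -0.00064 (no filter), -0.0011 (stricter filter), -0.0038 (DESeq2), -0.112 and -0.113 (TPM) and -0.10 to 0.11 (a library left out); Procr at -0.069 and -0.070 (TPM) and -0.059 to 0.14 (a library left out, -0.0029 without wild-type replicate 2); Slamf1 at -0.40 to 0.29 (0.029 without Dis3-/- replicate 1) and Malat1 at -0.18 to 0.030 (a library left out). In simulated counts at this depth, with 2 libraries per group, 49.3% of genes changed by a fold of 1.5 were recovered. Neither the depth nor the number of libraries was varied. That simulation changed 200 of 12244 genes, while 2811 were called in the data, so its recovery need not hold here.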

Other observations

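The counts of the class of long noncoding RNA genes, the test on progenitor lists, the overlap test in both annotations and the separate length tests for cell cycle and respiratory lists were chosen after the result was seen. Among 425 tested long noncoding RNA genes 87 rose and 17 fell by edgeR (49 and 15 without Dis3-/- replicate 2), with a median log2 fold change of 0.166 (0.166 also with genes at 0 in wild type set to their lower bound), against 1455 and 1226 of 11679 coding genes. A log2 fold change of at least 1 was reached by 78 of the 87. Among called genes 83.7% of noncoding and 54.3% of coding genes were higher (odds ratio 4.31, 95% interval 2.53 to 7.78, 2-sided Fisher exact p = 6.22e-10 over genes, which are not independent replicates). Camera gave p = 1.64e-03 for the class, and p = 0.198 with an estimated correlation.

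Some genes with wide rises lay near each other. Slc15a2 and BC031361 start 1334903 bp apart on chromosome 16. On chromosome X the coding gene Mid1, which spans the pseudoautosomal boundary, rose (20.7 ± 0.0720 against 84.4 ± 9.44 CPM, 2.03 ± 0.13, edgeR adjusted p = 6.42e-07), as did G530011O06Rik (35.7 ± 4.91 against 248 ± 11.3 CPM), which lies within Mid1, so that reads of the pair can be shared. Erdr1 rose by less (0.41 ± 0.10, edgeR adjusted p = 9.10e-03), a call that ended without wild-type replicate 2 (0.29, edgeR adjusted p = 0.0729) and on TPM values. Miat, a long noncoding RNA gene, had 0 wild-type counts and 16 and 28 Dis3-/- counts, at least 15.6-fold higher against the floor of 3 counts over the group.

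A first hypothesis is that the rise of long noncoding RNA genes reflects reduced decay by the exosome, strongest for transcripts that diverge from coding promoters. Low expression alone is argued against: the median of 0.166 lay at percentile 100 of 10000 draws of coding genes of the same mean expression, whose highest median was 0.0638. Length and GC content were not matched in these draws or in the overlap and divergence tests below. Removal of that trend took list medians from 0.133 to 0.026 (predicted models), 0.158 to 0 (antisense symbols) and 0.067 to 0.0512 (RIKEN models). It was not applied to the long noncoding class, so a part played by transcript length stays open. Reads shared with coding genes are argued against as the whole cause, since 132 long noncoding RNA genes overlapping no coding gene had a median of 0.444 (permutation p = 1e-04, the smallest the draws can give). Annotations differ on overlap: 16 of the 132, Gm5464 among them, overlap a coding gene in RefSeq but not in GENCODE, and the other 116 had a median of 0.364 (permutation p = 1e-04). The 156 genes starting within 2000 bp of a coding gene start on the other strand had a median higher by 0.324 than 201 others (2-sided permutation p = 2.2e-04), which is consistent with the hypothesis; positions were known for 357 of the 425 genes. Coding partners of the divergent genes had a median of 0.0552, with 25 higher and 15 lower of 138 tested. Whether greater transcription from these promoters played a part was not tested. The Mx-Cre transgene, present in Dis3-/- cells alone, is confounded with the deletion.

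The appearance of Slc15a2 may come from a chromosome segment of another strain carried with a modified allele, or from transcription running in from a neighbour. Both genotypes carried Dis3fl/fl, so of the modified alleles in the labels the Mx-Cre transgene alone differed between them. Within 3000000 bp, 1 of 40 other genes was called with a log2 fold change of at least 1 in size, against 4.28% elsewhere (2-sided Fisher exact p = 1), which neither shows nor excludes a segment. That gene was BC031361 (3.69 ± 0.33), and the test does not weigh how wide its rise was. The coding gene next upstream on its strand, Eaf2, had 0 and 2 wild-type and 2 and 2 Dis3-/- counts and was not tested; Fbxo40, the nearest tested gene, taken in its place, stood at 0.45 (edgeR adjusted p = 0.667). Slc15a2 stood at 40.5 CPM in the Dis3-/- libraries, where 3 counts amount to 0.505 and 0.469 CPM. The 2 and 2 counts of Eaf2 there argue against transcription running in through Eaf2 at a like level. A start elsewhere nearby was not tested. With so few genes in the window a linked segment cannot be told apart from the other explanations, and effects of the Dis3 deletion and of Cre stay open as well.

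The rise of cell cycle and growth genes may reflect stem cells that entered division after targeting of Dis3, or a technical shift. An admixture of lineage-primed progenitors, which the gates on CD48 and lineage markers are meant to remove, would raise genes of those lineages. Medians of the progenitor, granulocyte and erythroid lists were below 0, the highest at -0.252. That goes against such an admixture, but the criterion was set after these medians were seen, so it is no independent test. The stem cell list also fell (21 lower and 2 higher of 54, median -0.253), which an admixture would allow. Further limits are that the granulocyte list, with 5 tested genes, did not pass camera (adjusted p = 0.0730) and that the erythroid list passed in 8 of 15 alternative settings. With an estimated correlation the camera adjusted p = 0.293 for each of the 3 lineage lists. Library scaling moved the G2 and M phase median by 0.02. Fold changes fell with transcript length over genes (Spearman -0.230), but after removal of the median of genes of like length and GC content the G2 and M phase and S phase lists kept at least 98.0% of their medians, while the respiratory chain list kept 66.7% (camera adjusted p = 3.10e-10 with the preset correlation; before the removal, adjusted p = 0.293 with an estimated one), so that a part of its rise cannot be told apart from a length trend. A shift in which cells pass the sort and an effect of Cre itself stay open, as untested, as does an unequal exposure to pIpC.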
